A study of Mus musculus with 24 samples.

How the data were processed

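RNA was measured in 24 libraries of sorted tumour cells from 3 mouse lines, 4T07, D2A1 and EMT6, with 4 tumours per line and a p27K high and a p27K negative library per tumour. Per the labels' protocols, tumours were digested with collagenase IV, hyaluronidase and DNase, passed through a strainer and freed of red cells. Cells were stained for CD45, a marker of blood cells, and with DAPI, and sorted on an AriaIII by the mVenus reporter. RNA was taken up with the miRNeasy Micro kit and sequenced by GENEWIZ, which also made the count matrices, per the labels' protocols. The gate settings, library kit, strandedness, aligner and counter are not given in the sources used here. The submitters' processing notes name the genome build mm10 and DESeq2.

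The authors deposited whole-number gene counts that were not normalized, in a table per line. The 4T07 table had 24982 genes under symbols in capitals, of which 24038 were matched to symbols of the other tables, 507 to a reference symbol table and 437 kept as written. The D2A1 and EMT6 tables had 49316 entries each, including a totals entry and 176 entries with a blank name, which were left out. The blank names held at most 0.0109% of the counts of a D2A1 library and 0.0089% of an EMT6 library. Symbols on several entries were summed, and 4 entries per table with a date in place of a symbol that could not be told apart were left out. All 24 columns of counts were used, and 24034 symbols were in all 3 tables. Counting was by gene, so near-identical copies, overlapping genes and antisense partners may share or lose reads, since strand use is not known.

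Libraries were grouped by the line and gate in the labels. Both gates of a tumour are paired by the labels in 4T07 and D2A1. The EMT6 columns carry the numbers 0, 1, 2 and 4, which differ from the numbers in the titles, and were paired by these because same-numbered libraries deviated together (r of 0.615, 0.574, 0.813 and 0.648 over 5000 genes). The correlations were 0.801, 0.703, 0.609 and 0.195 in 4T07 and 0.112, 0.210, 0.0834 and 0.294 in D2A1, and each library correlated best with its own number. P-values measure the spread of the gate difference between tumours.

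Each line was tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with TMM scaling, default filtering of low counts and the tumour as a block. The standard error of a change was taken as its size over the square root of the F statistic. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. A joint fit of all libraries with 12 tumours as blocks gave the average change and a test of equal change in the 3 lines. Gene lists (38, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, if at least 5 members were tested. Camera compares a list with other genes, whereas fry does not. B and plasma cell and erythroid and platelet markers had too few tested members in every line. CPM values are scaled by TMM. Intervals and errors cover the spread of the gate difference between tumours and not the share of reads copied by PCR.

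Genes named in the text followed a rule fixed before the data were examined, except Lyz2, Apoe, C1qa, Ptprc, Col1a2, Pdpn, Cd34 and those of the plot of 6 transcripts, which were chosen after their values were seen. It took Cdkn1b and Mki67, per line the 6 highest and 6 lowest changes among called genes with the same sign in 4 of 4 pairs and a mean of at least 5 CPM, and 2 members of each list described, by smallest p. For the average it took the 10 rises and 10 falls with the smallest p among genes of the same sign in at least 11 of 12 tumours, and for the difference between lines the 6 smallest p. Predicted genes and pseudogenes were passed over, and some genes that the rule took are not reported here. Coordinates are those of GENCODE vM21 on GRCm38, the assembly that mm10 names, counted from 1.

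The procedure was tested on simulated data with real means and library sizes, 5 simulations per line. Of 250 changed genes per fold size, 47.2% were recovered at 1.5-fold, 80.4% at 2-fold, 94.0% at 4-fold and 98.4% at 8-fold in 4T07, over 12849 genes. In D2A1 (12845 genes) the shares were 41.2%, 74.8%, 94.4% and 99.6%, and in EMT6 (13354 genes) 73.2%, 84.8%, 98.4% and all. False calls made up 6.2%, 7.8% and 8.4% of calls in 4T07, D2A1 and EMT6, above the nominal 5%. For the average (13578 genes) 85.5% of 200 genes changed by 2-fold were recovered with 8.6% false calls, and for the difference 90% at 4-fold with 3.2%. A far smaller share of genes was changed in these simulations than was called in the real data. The shares recovered and falsely called may therefore differ in the real data. In list tests 15 of 15 raised lists and 0 of 15 unchanged lists had an unadjusted camera p under 0.05. Genes were simulated independently of each other, so these list tests could not check the preset correlation.

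Alternatives were a fit without the block, DESeq2 1.42.0, its size factors, total count scaling, no filter and a stricter filter on low counts, a log2 change of at least 1, voom with quality weights, other list tests, and leaving out each tumour in turn. Thinning of libraries, a restriction to genes tested in all 3 lines and total count scaling for lists were added after the data had been seen. Other splits of the libraries were counted: 35 per line, and 40 drawn for each joint test. Figures were drawn with matplotlib 3.10.9.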

Results

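Tumours of 3 mouse mammary carcinoma lines were compared by bulk RNA sequencing of their quiescent and proliferating cells. The lines 4T07, D2A1 and EMT6 carried mCherry and a reporter in which mVenus is joined to p27K, a form of the cell cycle inhibitor p27 that accumulates in resting cells. Each female Balb/cJ mouse received 250000 cells in a mammary fat pad, and tumours were taken on day 14. A p27K high and a p27K negative population were sorted from each tumour, giving 24 libraries from 12 tumours, with 4 tumours per line. The series title sets the question: what distinguishes quiescent tumour cells, which it links to resistance to T cells and to an immunosuppressive niche.

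The 4T07 libraries held 27887221 to 45460880 counts in the p27K high gate and 28961831 to 35197694 in the p27K negative gate. In EMT6 the ranges were 13769682 to 20142013 and 16988365 to 17508301 counts. In D2A1 the p27K high libraries held 6727594 to 20174767 counts. The p27K negative libraries of D2A1 tumours 1, 2 and 3 held 1335433, 2110563 and 1802042 counts and that of tumour 4 held 15641189. Precision for low genes is therefore lowest in D2A1, and lines were sequenced in separate runs. All changes are log2 of p27K high over p27K negative within tumours, with the standard error of the edgeR quasi-likelihood fit and n = 4 pairs per line.

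**Figure D1:**
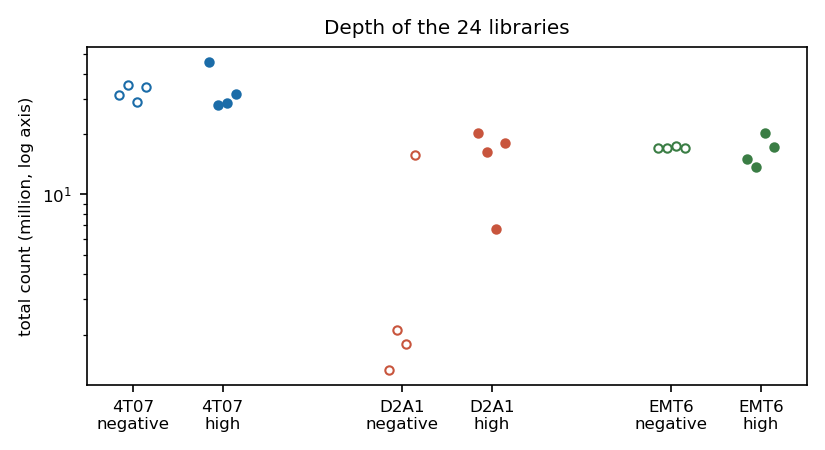
Total count of each library on a log axis, by line and gate; filled points are p27K high and open points p27K negative libraries. In D2A1, 3 of the 4 negative libraries lie between 1335433 and 2110563 counts, below every other library.

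The gates were first compared at the gene from which the reporter is built and at a proliferation marker. Cdkn1b, which encodes p27 (chromosome 6, 134920401 to 134925513, plus strand, mm10 coordinates, protein coding), rose in all 3 lines: by 0.89 ± 0.11 in 4T07, 0.46 ± 0.11 in D2A1 and 0.54 ± 0.04 in EMT6. Reads of the transduced reporter could also count towards this gene. Its mean level in 4T07 was 421 ± 104 CPM (counts scaled to library size; SD, n = 4) in the high gate and 222 ± 22.8 in the negative gate. In D2A1 the edgeR adjusted p was 0.00691, and without tumour 4 the change was 0.39 with an adjusted p of 0.0559. Mki67, the gene of the Ki-67 antigen of cycling cells (chromosome 7, 135689784 to 135716361, minus strand), changed by -6.52 ± 0.21, -5.92 ± 0.23 and -5.31 ± 0.09 in the same order. Its level in EMT6 went from 516 ± 46.8 CPM in the negative gate to 13.0 ± 1.65 CPM in the high gate (SD, n = 4).

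In 4T07, p27K high cells had far lower levels of mitotic and replication genes, higher levels of hypoxia, glycolysis and TGF-beta genes, and lower levels of macrophage and MHC class II transcripts. Only the cell cycle calls held with an estimated correlation, and those 5 lists had adjusted p = 0.144, 0.268, 0.144, 0.352 and 0.352 with an estimated correlation. Of 12849 genes tested, 2837 rose and 3031 fell at an adjusted p under 0.05, 397 and 1323 of them by at least 2-fold. The highest rises among genes of at least 5 CPM were Ogn, a small matrix proteoglycan (3.48 ± 0.14), Gdpd2 (2.99 ± 0.18), the lipid droplet gene Plin4 (2.96 ± 0.23), Angptl7 (2.74 ± 0.12), the interleukin receptor gene Il13ra2 (2.73 ± 0.23) and Enpp2, which encodes autotaxin (2.39 ± 0.12). The lowest were the helicase gene Pif1 (-7.15 ± 0.38), the mitotic kinesin gene Kif18b (-7.05 ± 0.28), Pimreg (-7.00 ± 0.29), Pbk (-6.96 ± 0.28), Ankle1 (-6.91 ± 0.37) and the separase gene Espl1 (-6.84 ± 0.32). These 12 were taken from called genes with the same sign in 4 of 4 tumours, so that agreement was set by the choice.

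Gene lists fixed beforehand were then tested in 4T07, with counts adjusted over the list alone equal to those over all genes unless given. Among G1/S genes 0 of 50 tested members rose, 50 fell and 0 did not pass the test, led by Clspn (-5.05 ± 0.13) and the ribonucleotide reductase gene Rrm1 (-2.94 ± 0.08). The G1/S median was -2.79 (camera adjusted p = 6.55e-84, or adjusted p = 0.0307 with an estimated correlation). Among G2/M genes 0 of 59 tested members rose, 59 fell and 0 did not pass the test, including Kif23 (-5.59 ± 0.10) and the cyclin gene Ccna2 (-6.19 ± 0.13). The G2/M median was -5.48 (camera adjusted p = 9.71e-203, or adjusted p = 0.0342 with an estimated correlation). For targets of the hypoxia factor HIF1A, 29 of 41 tested members rose, 3 fell and 9 did not pass the test, with Ndrg1 at 2.13 ± 0.09 and the carbonic anhydrase gene Car9 at 2.36 ± 0.11. The hypoxia median was 0.95 (camera adjusted p = 2.29e-14, or adjusted p = 0.144 with an estimated correlation). Glycolysis enzymes moved with them: 14 of 15 tested members rose, 0 fell and 1 did not pass the test, such as Eno2 (1.62 ± 0.07) and Hk2 (1.11 ± 0.07). The glycolysis median was 0.73 (camera adjusted p = 2.58e-08, or adjusted p = 0.268 with an estimated correlation). In the TGF-beta list 17 of 29 tested members rose, 3 fell and 9 did not pass the test (18 rose and 3 fell adjusted over the list alone), with Ctgf at 2.05 ± 0.09 and Tgfbr3 at 2.15 ± 0.11. The TGF-beta median was 0.37 (camera adjusted p = 7.9e-05, or adjusted p = 0.144 with an estimated correlation). Of dormancy genes, 9 of 18 tested members rose, 2 fell and 7 did not pass the test (9 rose and 3 fell adjusted over the list alone), among them Dcn, which encodes decorin (2.11 ± 0.10). The dormancy median was 0.41 (camera adjusted p = 0.000285, or adjusted p = 0.163 with an estimated correlation).

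Other called lists of 4T07 covered ribosomal proteins, cholesterol synthesis, autophagy and mesenchymal genes. For cytosolic ribosomal proteins 42 of 77 tested members rose, 0 fell and 35 did not pass the test (45 rose and 0 fell adjusted over the list alone), with Rpl5 at 0.65 ± 0.09 and Rps7 at 0.49 ± 0.07. The ribosomal protein median was 0.32 (camera adjusted p = 0.000219, or adjusted p = 0.226 with an estimated correlation). Many ribosomal protein genes have near-identical pseudogene copies, so their counts are uncertain. In cholesterol synthesis 0 of 22 tested members rose, 14 fell and 8 did not pass the test (0 rose and 15 fell adjusted over the list alone), including Fdps (-1.21 ± 0.11). The cholesterol median was -0.56 (camera adjusted p = 0.00507, or adjusted p = 0.226 with an estimated correlation). Among autophagy and lysosome genes 15 of 36 tested members rose, 2 fell and 19 did not pass the test, with Gabarapl1 at 1.10 ± 0.10 and Sqstm1 at 1.03 ± 0.10. The autophagy median was 0.16 (camera adjusted p = 0.00566, or adjusted p = 0.544 with an estimated correlation). Of mesenchymal genes 15 of 36 tested members rose, 8 fell and 13 did not pass the test, among them the protease gene Mmp2 (2.10 ± 0.10) and the fibronectin gene Fn1 (1.33 ± 0.08). The mesenchymal median was 0.16 (camera adjusted p = 0.0184, or adjusted p = 0.226 with an estimated correlation). Scaling by total count moved the median of all 4T07 genes by -0.14 on the log2 scale, and the ribosomal protein, TGF-beta, autophagy and mesenchymal medians were then 0.19, 0.23, 0.02 and 0.03. The autophagy median was 0.27 without tumour 2, and the mesenchymal median 0.28 with a stricter filter on low counts. Without the tumour block the mesenchymal call was lost (camera adjusted p = 0.0916).

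Macrophage, MHC class II, neutrophil and chemokine lists were called down in 4T07, each lost with an estimated correlation. All 25 macrophage and monocyte markers tested fell, with the immune adaptor gene Tyrobp at -2.85 ± 0.21 and the complement gene C1qb at -2.93 ± 0.22. The macrophage median was -2.47 (camera adjusted p = 1.28e-11, or adjusted p = 0.352 with an estimated correlation). All 9 tested MHC class II genes fell, including H2-Ab1 (-1.37 ± 0.08) and H2-Aa (-1.27 ± 0.10). The MHC class II median was -1.27 (camera adjusted p = 7.12e-06, or adjusted p = 0.352 with an estimated correlation). Neutrophil markers also fell as a list: 0 of 12 tested members rose, 7 fell and 5 did not pass the test, with Clec4d at -1.91 ± 0.24 and Csf3r at -1.96 ± 0.25. The neutrophil median was -1.29 (camera adjusted p = 0.0271, or adjusted p = 0.504 with an estimated correlation). For chemokines and cytokines 7 of 36 tested members rose, 18 fell and 11 did not pass the test (7 rose and 22 fell adjusted over the list alone), including Cxcl10 (-1.76 ± 0.11) and Cxcl16 (-1.90 ± 0.14). The chemokine median was -0.85 (camera adjusted p = 0.0225, or adjusted p = 0.523 with an estimated correlation). The neutrophil call was lost without tumour 2 or 3 and the chemokine call without tumour 2 (camera adjusted p = 0.0565, 0.0511 and 0.0843). In the p27K high library of tumour 2, 13500 genes were detected, against 15094 to 15370 in the other high libraries of 4T07. The chemokine call was also lost among genes tested in all 3 lines (camera adjusted p = 0.769). The chemokine median was -0.53 without tumour 2, -0.54 with a stricter filter on low counts and -0.12 among genes tested in all 3 lines. Lyz2, a macrophage gene chosen after its values were seen, went from 194 ± 104 CPM in the negative gate to 23.7 ± 2.31 CPM in the high gate (SD, n = 4). Fibroblast markers went up: 7 of 17 tested members rose, 1 fell and 9 did not pass the test, with Ogn and Dcn among the rises. The fibroblast median was 0.45 (camera adjusted p = 0.000693, or adjusted p = 0.352 with an estimated correlation). Without the tumour block the neutrophil and fibroblast calls were lost (camera adjusted p = 0.0522 for each), and without tumour 3 the fibroblast median was 0.75.

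Checkpoint ligands and immunosuppressive factors went both ways in 4T07: 9 of 36 tested members rose, 11 fell and 16 did not pass the test (10 rose and 13 fell adjusted over the list alone). Their mean was -0.44, while the list test pointed up without passing. The checkpoint median was -0.02 (camera adjusted p = 0.877, or adjusted p = 0.892 with an estimated correlation). The inducible nitric oxide synthase gene Nos2 rose by 1.16 ± 0.07 and Vegfa, the angiogenic growth factor, by 1.28 ± 0.10. In all, 15 of 35 lists were called in 4T07, and 2 of them, the cell cycle lists, held with an estimated correlation. Without tumour 1 the number of changed genes was 3698 in place of 5868, and scaling by total count alone gave 1908 rises among 5752 changed genes (33.2% in place of 48.3%).

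**Figure D2:**
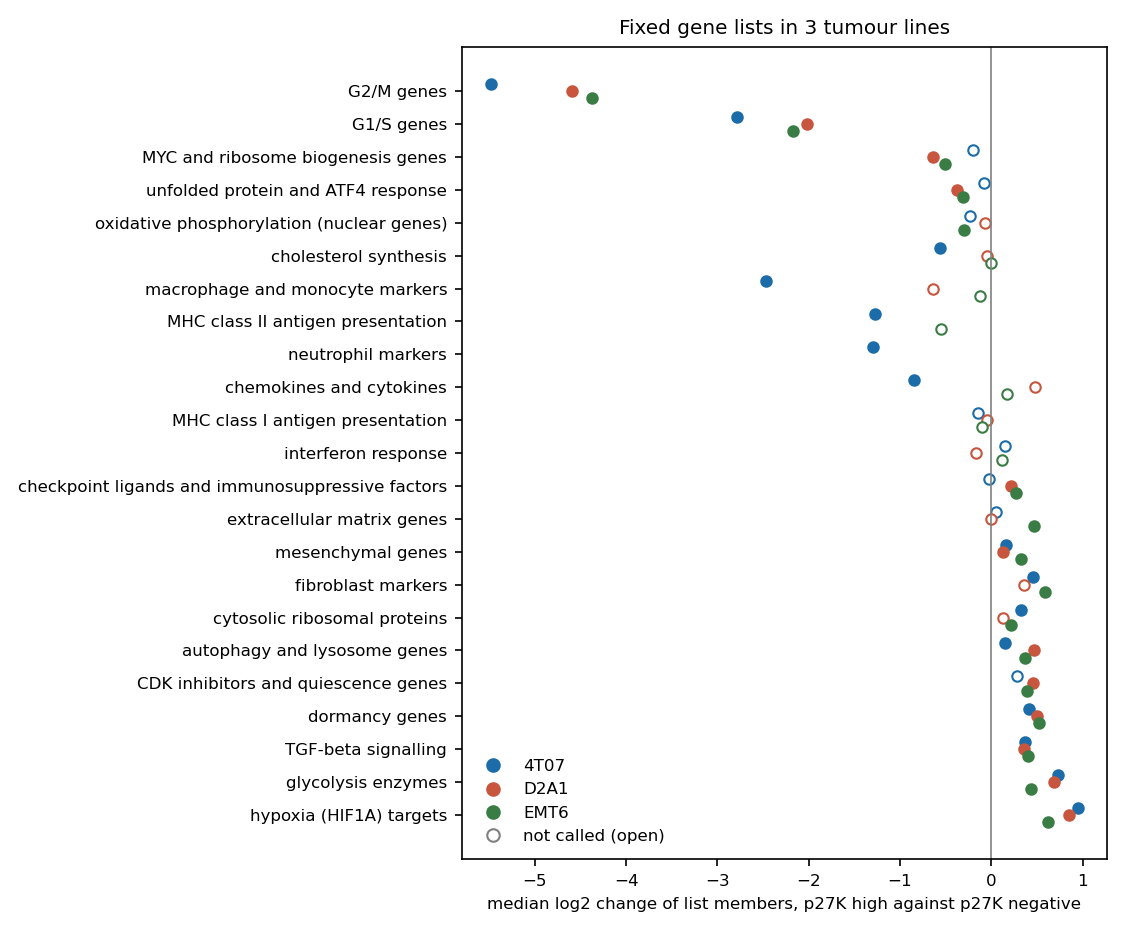
Median log2 change of the members of 23 gene lists, p27K high against p27K negative, in 3 lines; a filled point marks a list called by camera with its preset correlation and an open point a list not called, and lists with too few tested genes have no point. G2/M medians lie at -5.48, -4.59 and -4.37 and hypoxia medians at 0.95, 0.85 and 0.63, while the macrophage median is -2.47 in 4T07. Calls other than the G1/S and G2/M ones of 4T07 and EMT6 are lost with an estimated correlation.

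In D2A1, p27K high cells again had lower cell cycle genes and higher hypoxia and glycolysis genes, together with higher NF-kB targets and lower MYC targets. The matrix list, which was not called, held 15 falls beside 11 rises. With an estimated correlation camera called 0 of the D2A1 lists, with 5 at an unadjusted p under 0.05, and fry called 14. Of 12845 genes tested, 1912 rose and 1882 fell, 458 and 636 of them by at least 2-fold. Genes named next were taken from those of at least 5 CPM with the same sign in 4 of 4 tumours. The highest rises among these were the angiotensinogen gene Agt (3.28 ± 0.35), Angptl7 (3.18 ± 0.35), the noradrenaline transporter gene Slc6a2 (3.18 ± 0.22), Hsd11b1, which regenerates active glucocorticoid (3.17 ± 0.18), the matrix gene Aspn (2.95 ± 0.14) and Plin4 (2.88 ± 0.33). The lowest among them were Kif14 (-6.36 ± 0.25), Aspm (-6.15 ± 0.21), Neil3 (-6.13 ± 0.34), Kif2c (-6.05 ± 0.23), the collagen gene Col5a2 (-5.97 ± 0.34) and Mki67 (-5.92 ± 0.23).

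By list, G1/S and G2/M genes fell in D2A1. For G1/S genes 0 of 50 tested members rose, 49 fell and 1 did not pass the test, with Rrm2 at -3.93 ± 0.17 and Mcm10 at -4.28 ± 0.19. The G1/S median was -2.02 (camera adjusted p = 4.26e-66, or adjusted p = 0.172 with an estimated correlation). For G2/M genes 0 of 60 tested members rose, 60 fell and 0 did not pass the test, with Cenpe at -5.48 ± 0.15 and Pbk at -5.09 ± 0.14. The G2/M median was -4.59 (camera adjusted p = 4.41e-281, or adjusted p = 0.0539 with an estimated correlation). Among hypoxia targets 29 of 40 tested members rose, 3 fell and 8 did not pass the test (30 rose and 3 fell adjusted over the list alone), including Ndrg1 (1.75 ± 0.11) and the mitophagy gene Bnip3 (1.67 ± 0.11). The hypoxia median was 0.85 (camera adjusted p = 9.97e-13, or adjusted p = 0.271 with an estimated correlation). Of glycolysis enzymes 14 of 16 tested members rose, 0 fell and 2 did not pass the test (15 rose and 0 fell adjusted over the list alone), with Eno2 at 1.89 ± 0.13 and Hk2 at 1.22 ± 0.13. The glycolysis median was 0.69 (camera adjusted p = 1.56e-07, or adjusted p = 0.423 with an estimated correlation). In TGF-beta signalling 16 of 31 tested members rose, 0 fell and 15 did not pass the test (19 rose and 1 fell adjusted over the list alone), with Tgfbr3 at 1.63 ± 0.12 and Ltbp2 at 0.88 ± 0.11. The TGF-beta median was 0.36 (camera adjusted p = 0.000368, or adjusted p = 0.202 with an estimated correlation). Of dormancy genes 9 of 20 tested members rose, 2 fell and 9 did not pass the test (10 rose and 2 fell adjusted over the list alone), such as Bhlhe41 (1.42 ± 0.17). The dormancy median was 0.50 (camera adjusted p = 0.0164, or adjusted p = 0.289 with an estimated correlation). CDK inhibitors and quiescence genes were called here: 17 of 30 tested members rose, 2 fell and 11 did not pass the test, with Gas1 at 1.37 ± 0.11 and Pik3ip1 at 1.45 ± 0.15. The quiescence median was 0.45 (camera adjusted p = 0.000483, or adjusted p = 0.202 with an estimated correlation).

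In D2A1 the MYC and unfolded protein lists were called down, and the autophagy, immediate-early, NF-kB and checkpoint lists up. Of MYC and ribosome biogenesis genes 0 of 30 tested members rose, 24 fell and 6 did not pass the test (0 rose and 26 fell adjusted over the list alone), with Dkc1 at -1.42 ± 0.12 and Tcof1 at -1.36 ± 0.12. The MYC median was -0.64 (camera adjusted p = 2.91e-08, or adjusted p = 0.442 with an estimated correlation). In the unfolded protein and ATF4 list 3 of 30 tested members rose, 15 fell and 12 did not pass the test (5 rose and 17 fell adjusted over the list alone). The unfolded protein median was -0.37 (camera adjusted p = 0.0156, or adjusted p = 0.706 with an estimated correlation). Its leading falls, Psat1 (-1.73 ± 0.12) and Shmt2 (-1.16 ± 0.12), are enzymes of serine and one-carbon metabolism. Autophagy and lysosome genes rose: 23 of 36 tested members rose, 0 fell and 13 did not pass the test (27 rose and 0 fell adjusted over the list alone), with Ctsa at 0.97 ± 0.12 and Neu1 at 1.36 ± 0.18. The autophagy median was 0.47 (camera adjusted p = 1.86e-05, or adjusted p = 0.369 with an estimated correlation). For immediate-early and heat-shock genes 15 of 32 tested members rose, 2 fell and 15 did not pass the test (16 rose and 2 fell adjusted over the list alone), with Dusp1 at 0.99 ± 0.11 and Ier3 at 0.97 ± 0.13. The immediate-early median was 0.37 (camera adjusted p = 0.00589, or adjusted p = 0.474 with an estimated correlation). Among NF-kB targets 13 of 24 tested members rose, 1 fell and 10 did not pass the test (14 rose and 1 fell adjusted over the list alone), with the lipocalin gene Lcn2 at 2.66 ± 0.23 and Saa3 at 1.93 ± 0.26. The NF-kB median was 0.45 (camera adjusted p = 0.00487, or adjusted p = 0.474 with an estimated correlation). Among checkpoint ligands and immunosuppressive factors 12 of 28 tested members rose, 2 fell and 14 did not pass the test, with Vegfa at 1.47 ± 0.11 and Vsir, the gene of the checkpoint protein VISTA, at 1.83 ± 0.14. The checkpoint median was 0.21 (camera adjusted p = 0.0258, or adjusted p = 0.289 with an estimated correlation).

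Mesenchymal genes of D2A1 were called up narrowly: 16 of 40 tested members rose, 7 fell and 17 did not pass the test (18 rose and 8 fell adjusted over the list alone), with Mmp3 at 1.81 ± 0.14 and Mmp2 at 1.54 ± 0.13. The mesenchymal median was 0.13 (camera adjusted p = 0.0476, or adjusted p = 0.289 with an estimated correlation). That call was lost without tumour 1, 2 or 4 (camera adjusted p = 0.0803, 0.0737 and 0.0679), and the unfolded protein call without tumour 4 (camera adjusted p = 0.0679). Without the tumour block the mesenchymal call was lost too (camera adjusted p = 0.0731). The mesenchymal median was 0.064 without tumour 3, 0.20 without tumour 4 and 0.36 with all libraries thinned to the smallest. The checkpoint median of D2A1 was 0.40 without tumour 4. Extracellular matrix genes split: 11 of 43 tested members rose, 15 fell and 17 did not pass the test (12 rose and 15 fell adjusted over the list alone). Their mean was -0.72, and the list test pointed down without passing. The matrix median was -0.000677 (camera adjusted p = 0.257, or adjusted p = 0.716 with an estimated correlation). Col5a2 (chromosome 1, 45374321 to 45503282, minus strand) went from 28.3 ± 8.90 CPM in the negative gate to 0.405 ± 0.185 CPM in the high gate (SD, n = 4), and the periostin gene Postn fell by 1.94 on the log2 scale. Col1a2, chosen after its values were seen, went from 127 ± 12.9 to 10.8 ± 10.0 CPM. The fibroblast list did not pass: 7 of 16 tested members rose, 2 fell and 7 did not pass the test (8 rose and 2 fell adjusted over the list alone). The fibroblast median was 0.35 (camera adjusted p = 0.199, or adjusted p = 0.474 with an estimated correlation). Its mean was -0.08, of the other sign than its median. It passed upwards with a stricter filter on low counts, with all libraries thinned to the smallest and without tumour 4 (camera adjusted p = 0.00606, 0.000422 and 0.0244). The matrix list passed downwards without tumour 2, at a median of 0.02 (camera adjusted p = 0.00709).

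In all, 14 of 32 lists were called in D2A1. Chemokines and cytokines were not called (median 0.48) but were with a stricter filter and with all libraries thinned (camera adjusted p = 0.0124 and 0.0178). Oxidative phosphorylation genes were called down only without tumour 3 and ribosomal proteins up only without tumour 4 (camera adjusted p = 0.00226 and 0.0347). Without tumour 1 the number of changed genes was 2444 in place of 3794.

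In EMT6, p27K high cells had lower cell cycle genes and higher hypoxia targets, with matrix and fibroblast genes higher and oxidative phosphorylation genes slightly lower. Only the cell cycle calls among these held with an estimated correlation, the others having adjusted p = 0.153, 0.392, 0.207 and 0.601 with an estimated correlation. Of 13354 genes tested, 3215 rose and 3352 fell, 311 and 556 of them by at least 2-fold. The highest rises among genes of at least 5 CPM were Aspn (3.06 ± 0.27), Gdpd2 (2.80 ± 0.21), Galnt15 (2.79 ± 0.33), Pyroxd2 (2.45 ± 0.15), Tcp11l2 (2.45 ± 0.12) and the cholesterol exporter gene Abca1 (2.33 ± 0.19). The lowest were the kinesin genes Kif11 (-6.35 ± 0.19), Kif14 (-6.30 ± 0.19) and Kif2c (-5.85 ± 0.15), with Ankle1 (-6.20 ± 0.24), Neil3 (-6.04 ± 0.37) and Nusap1 (-5.90 ± 0.15). These too were taken from called genes with the same sign in 4 of 4 tumours.

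All 50 G1/S genes of EMT6 fell, with Rrm1 at -2.46 ± 0.05. The G1/S median was -2.17 (camera adjusted p = 8.02e-103, or adjusted p = 0.0238 with an estimated correlation). All 60 G2/M genes fell, with Cenpe at -4.85 ± 0.07 and Bub1b at -4.80 ± 0.07. The G2/M median was -4.37, called by camera, with adjusted p = 0.0238 with an estimated correlation. For hypoxia targets 38 of 40 tested members rose, 0 fell and 2 did not pass the test (39 rose and 0 fell adjusted over the list alone), with the glucose transporter gene Slc2a1 at 0.89 ± 0.04 and Car9 at 1.27 ± 0.06. The hypoxia median was 0.63 (camera adjusted p = 4.11e-17, or adjusted p = 0.153 with an estimated correlation). For glycolysis enzymes 15 of 16 tested members rose, 0 fell and 1 did not pass the test, with Aldoc at 1.53 ± 0.07 and Eno2 at 1.27 ± 0.07. The glycolysis median was 0.44 (camera adjusted p = 9.59e-07, or adjusted p = 0.396 with an estimated correlation). In TGF-beta signalling 24 of 31 tested members rose, 1 fell and 6 did not pass the test (24 rose and 2 fell adjusted over the list alone), with Thbs1 at 0.82 ± 0.04 and Itgb8 at 1.38 ± 0.08. The TGF-beta median was 0.41 (camera adjusted p = 3.3e-06, or adjusted p = 0.207 with an estimated correlation). Of dormancy genes 16 of 20 tested members rose, 1 fell and 3 did not pass the test, Ndrg1 being at 1.39 ± 0.08. The dormancy median was 0.52 (camera adjusted p = 0.000117, or adjusted p = 0.127 with an estimated correlation). CDK inhibitors and quiescence genes rose as a list: 18 of 29 tested members rose, 5 fell and 6 did not pass the test, with Btg1 at 0.69 ± 0.04 beside Cdkn1b. The quiescence median was 0.39 (camera adjusted p = 0.0126, or adjusted p = 0.564 with an estimated correlation).

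In EMT6 the MYC, oxidative phosphorylation and unfolded protein lists were called down, and ribosomal proteins, autophagy and immediate-early genes up. Of MYC and ribosome biogenesis genes 1 of 30 tested members rose, 26 fell and 3 did not pass the test (1 rose and 27 fell adjusted over the list alone), with Tcof1 at -1.33 ± 0.05 and the pyrimidine synthesis gene Cad at -0.89 ± 0.05. The MYC median was -0.51 (camera adjusted p = 9.59e-07, or adjusted p = 0.497 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell: 2 of 56 tested members rose, 44 fell and 10 did not pass the test, with Cyc1 at -0.70 ± 0.05 and Cycs at -0.91 ± 0.07. The oxidative phosphorylation median was -0.30 (camera adjusted p = 0.000568, or adjusted p = 0.601 with an estimated correlation). In the unfolded protein and ATF4 list 6 of 29 tested members rose, 19 fell and 4 did not pass the test, led by the serine synthesis genes Psat1 (-0.94 ± 0.07) and Phgdh (-0.75 ± 0.06). The unfolded protein median was -0.31 (camera adjusted p = 0.0183, or adjusted p = 0.497 with an estimated correlation). Cytosolic ribosomal proteins rose: 70 of 81 tested members rose, 3 fell and 8 did not pass the test (71 rose and 3 fell adjusted over the list alone), with Rps27 at 0.46 ± 0.04. The ribosomal protein median was 0.22 (camera adjusted p = 3.97e-06, or adjusted p = 0.392 with an estimated correlation). Of autophagy and lysosome genes 27 of 36 tested members rose, 0 fell and 9 did not pass the test, with Ctsa at 0.88 ± 0.05 and Map1lc3b at 0.57 ± 0.04. The autophagy median was 0.37 (camera adjusted p = 3.87e-06, or adjusted p = 0.110 with an estimated correlation). Among immediate-early and heat-shock genes 21 of 32 tested members rose, 6 fell and 5 did not pass the test, with Dusp6 at 0.74 ± 0.07 and Klf6 at 0.37 ± 0.04. The immediate-early median was 0.29 (camera adjusted p = 0.0472, or adjusted p = 0.497 with an estimated correlation). That call was lost without tumour 4 (camera adjusted p = 0.0515), under scaling by total count (0.0581) and with a stricter filter on low counts (0.0529).

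The mesenchymal, matrix, fibroblast and checkpoint lists were called up in EMT6. Of mesenchymal genes 20 of 38 tested members rose, 3 fell and 15 did not pass the test (21 rose and 3 fell adjusted over the list alone), and of extracellular matrix genes 23 of 41 tested members rose, 5 fell and 13 did not pass the test (24 rose and 5 fell adjusted over the list alone). The mesenchymal median was 0.33 (camera adjusted p = 0.000158, or adjusted p = 0.127 with an estimated correlation). The matrix median was 0.47 (camera adjusted p = 9.84e-05, or adjusted p = 0.392 with an estimated correlation). The thrombospondin genes Thbs2 (1.71 ± 0.07) and Thbs1 belong to both lists. Fibroblast markers rose: 8 of 14 tested members rose, 0 fell and 6 did not pass the test, with Ogn at 1.26 ± 0.04 and Pdgfra at 0.81 ± 0.09. The fibroblast median was 0.59 (camera adjusted p = 0.00861, or adjusted p = 0.207 with an estimated correlation). Among checkpoint ligands and immunosuppressive factors 16 of 31 tested members rose, 6 fell and 9 did not pass the test (17 rose and 7 fell adjusted over the list alone), with Vegfa at 1.04 ± 0.05 and Nos2 at 1.87 ± 0.12. The checkpoint median was 0.27 (camera adjusted p = 0.0333, or adjusted p = 0.251 with an estimated correlation). Without the tumour block, the checkpoint, fibroblast, immediate-early and unfolded protein calls were lost (camera adjusted p = 0.138, 0.0679, 0.0753 and 0.0520). Without tumour 0 the mesenchymal and checkpoint medians were 0.20 and 0.15. In all, 17 of 31 lists were called, and the 2 cell cycle lists held with an estimated correlation.

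**Figure D3:**
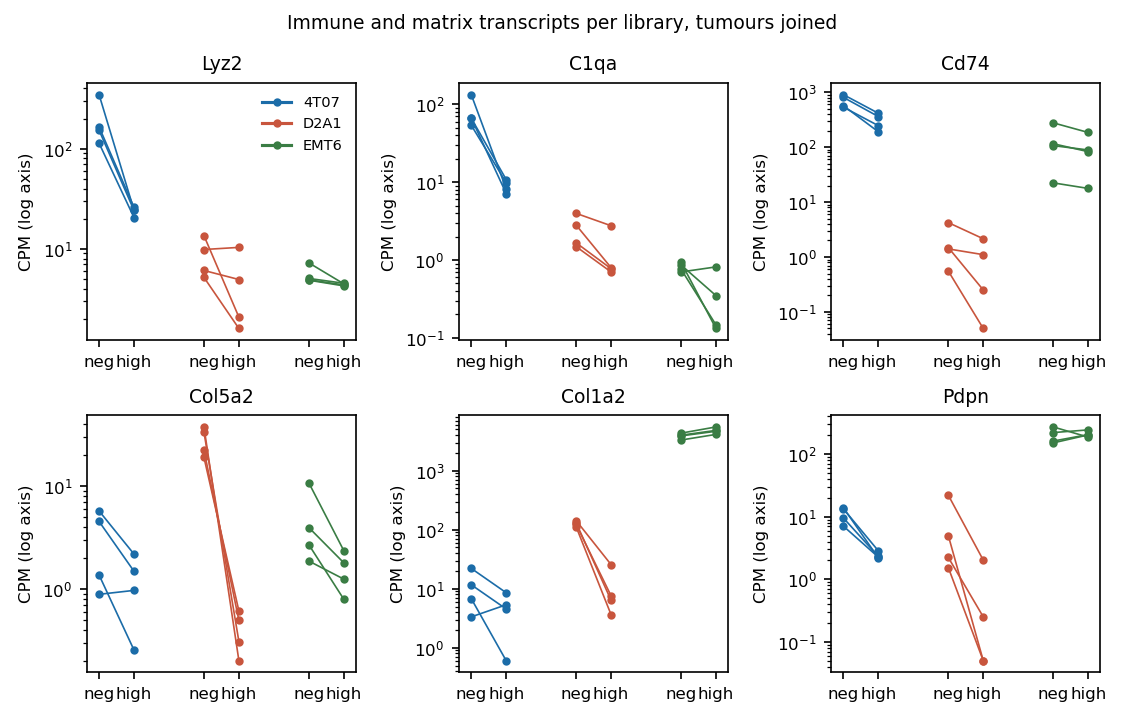
Levels in CPM of 6 transcripts in each library on a log axis, chosen after their values were seen; each line joins the p27K negative (neg) and p27K high (high) library of a tumour, colours mark the lines and values under 0.05 are drawn at 0.05. Lyz2 went from a mean of 194 to 23.7 CPM in 4T07 and Col5a2 from 28.3 to 0.405 CPM in D2A1.

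Averaged over the 3 lines in a fit of all 24 libraries, p27K high cells had lower cell cycle genes and higher hypoxia targets, TGF-beta signalling and dormancy genes, by list tests that held with an estimated correlation. Of 13578 genes tested, 3845 rose and 3265 fell, 364 and 846 of them by at least 2-fold. The rises with the smallest p were Ndrg1 (1.79 ± 0.05), Enpp2 (2.11 ± 0.07), Eno2 (1.63 ± 0.05), the prolyl hydroxylase gene P4ha2 (1.26 ± 0.04), Tgfbr3 (1.52 ± 0.06), Tcp11l2 (2.12 ± 0.08), Vegfa (1.29 ± 0.05), Dnm1 (1.15 ± 0.05), Slc2a1 (1.41 ± 0.06) and the kinase gene Tec (1.54 ± 0.07). Ndrg1 lies on chromosome 15, 66929318 to 66969640, minus strand, and its edgeR adjusted p was 1.23e-14. The falls with the smallest p were genes of chromosome condensation, spindle and cytokinesis: Kif23 (-5.15 ± 0.06), Ncapg (-4.91 ± 0.07), Racgap1 (-4.22 ± 0.06), Cdca8 (-4.69 ± 0.07), Cep55 (-5.87 ± 0.09), Mad2l1 (-3.31 ± 0.05), Tpx2 (-4.90 ± 0.08), Ncapd2 (-3.56 ± 0.06), Cenpe (-5.39 ± 0.09) and Bub1b (-5.35 ± 0.09). Kif23 lies on chromosome 9, 61915905 to 61946774, minus strand, with an edgeR adjusted p of 7.1e-19. Each of the 20 moved the same way in 12 of 12 tumours.

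**Figure D4:**
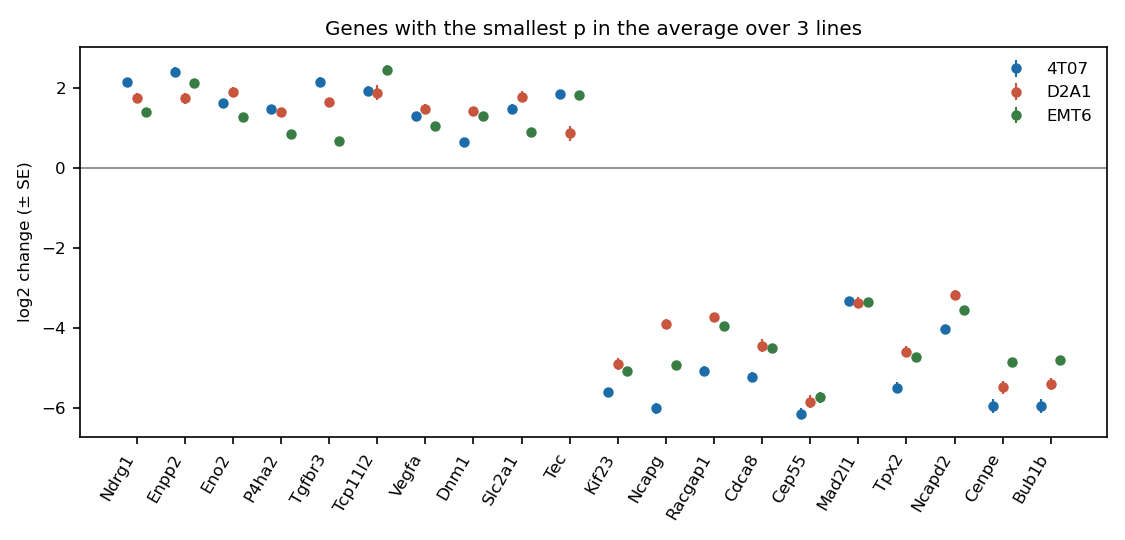
Log2 change, p27K high against p27K negative, of the 20 genes with the smallest p in the average over 3 lines; points are the estimates of each line from 4 tumours and bars the standard errors. The 10 rises lie above 0 and the 10 falls below 0 in each line, with Cep55 at -6.14, -5.83 and -5.72.

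In this average 11 of 35 lists were called, and 5 held with an estimated correlation. These 5 were G1/S genes (median -2.31), G2/M genes (-4.72), hypoxia targets (0.80, adjusted p = 0.0179 with an estimated correlation), TGF-beta signalling (0.39) and dormancy genes (0.37). In the hypoxia list 32 of 42 tested members rose, 5 fell and 5 did not pass the test (32 rose and 6 fell adjusted over the list alone). The other 6 calls were lost: glycolysis (0.66, adjusted p = 0.131 with an estimated correlation), autophagy (0.36, 0.239), MYC targets (-0.48, 0.414), quiescence genes (0.33, 0.354), immediate-early genes (0.29, 0.414) and ribosomal proteins (0.25, 0.923). MHC class I genes were not called (median -0.09), nor was the interferon response (median 0.09). Without the tumour block the quiescence and immediate-early calls were lost (camera adjusted p = 0.0680 and 0.0563). Mesenchymal genes (median 0.16) were not called, but were with a stricter filter (camera adjusted p = 0.0273). They were also called without 4T07 tumour 3, D2A1 tumour 4, EMT6 tumour 0 or EMT6 tumour 4 (camera adjusted p = 0.0483, 0.0321, 0.0270 and 0.0261). Oxidative phosphorylation genes were called down without 4T07 tumour 2 or D2A1 tumour 3 (camera adjusted p = 0.0471 and 0.00828), and fibroblast markers up without D2A1 tumour 2 (camera adjusted p = 0.0311). Under scaling by total count the ribosomal protein median was 0.16. Scaling by total count alone gave 2829 rises among 6918 changed genes (40.9% in place of 54.1%).

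The calls of the lines overlapped more than independent lists would. Of 10773 genes tested in all 3 lines, 691 rose and 1036 fell in all 3, against 103.5 and 113.9 for independent lists, and 337 rose in 1 line and fell in another. Across genes, which are not independent replicates, log2 changes correlated with Pearson's r of 0.72 (Spearman's rho 0.46) between 4T07 and D2A1, 0.80 (0.60) between 4T07 and EMT6 and 0.83 (0.71) between D2A1 and EMT6. Of genes tested in both, 4T07 and D2A1 shared 825 rises where independent lists would share 414.7 (Fisher's exact test, 1-sided, p = 1.57e-123), and 1105 falls against 402.5. The lines share no library, but all were sorted by the same cell cycle reporter. Shared falls of cell cycle genes therefore follow from the sort, and independent lists serve only as a reference. Overlap and correlation without the cell cycle genes were not tested.

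The changes themselves were then tested for a difference between lines. For 3332 of 13578 genes the change differed, and 2060 of these had fitted changes of opposite sign in at least 1 pair of lines. These signs were counted whatever the size of the change, so small changes that passed no test counted too. By the tests within lines, 337 of 10773 genes were called up in 1 line and down in another. In pairwise tests 3161 genes differed between 4T07 and D2A1, 2039 between 4T07 and EMT6 and 468 between D2A1 and EMT6. Line and sequencing run cannot be told apart in these tests, and 4T07 also had a count table of another form. That table held 24982 genes under symbols in capitals, against 49316 entries in each of the others. Whether this contributed to the counts for pairs with 4T07 was not tested. The 6 genes with the smallest p were Cit, Ccdc18, Ptgs2, Bard1, Anpep and Gstcd. Cit, the citron kinase gene of cytokinesis (chromosome 5, 115845278 to 116008947, plus strand), changed by -5.24 ± 0.14 in 4T07, -3.54 ± 0.15 in D2A1 and -1.80 ± 0.06 in EMT6. Ptgs2, which encodes the prostaglandin synthase COX-2 (chromosome 1, 150100031 to 150108227, plus strand), rose in 4T07 (1.59 ± 0.14) and EMT6 (0.49 ± 0.05) and fell in D2A1 (-3.25 ± 0.29), with an edgeR adjusted p of 5.05e-08 for the difference. Ccdc18 fell in 4T07 (-3.72 ± 0.15) and EMT6 (-3.53 ± 0.24) and was at 0.06 ± 0.14 in D2A1. Bard1, a partner of BRCA1, fell by different amounts (-4.97 ± 0.13, -3.15 ± 0.15 and -1.84 ± 0.11). The aminopeptidase gene Anpep fell in 4T07 (-1.35 ± 0.14) and rose in D2A1 (1.69 ± 0.15) and EMT6 (1.09 ± 0.08). Gstcd rose in D2A1 (0.66 ± 0.11) and fell in 4T07 (-0.90 ± 0.10) and EMT6 (-1.10 ± 0.05). Without the tumour block 1607 genes differed.

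As lists, macrophage markers had lower changes in 4T07 than in D2A1 (median difference -2.20) or EMT6 (-2.12). Of the 25 members in this joint test, 11 passed the filter on low counts in D2A1 and 10 in EMT6, where the list was not called. C1qa, chosen after its values were seen, stood at 2.48 CPM in the negative gate of D2A1 and 0.816 in that of EMT6. MHC class II genes had lower changes in 4T07 than in EMT6 (-0.82), where they were not called either. G1/S and G2/M genes fell in each line, and G2/M genes fell further in 4T07 than in D2A1 (-0.69) or EMT6 (-0.73). Cholesterol synthesis genes had lower changes in 4T07 than in D2A1 (-0.60) or EMT6 (-0.46), where that list was not called (medians -0.05 and -0.00255). Of 105 such tests, 40 passed (camera, preset correlation, adjusted over the tests).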

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

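Of the tests below, the comparison of depth by thinning and the counts of other splits were laid down before their results were seen. The test on the spread of the gate difference in D2A1 was chosen after the results had been seen. So were those on immune, fibroblast and endothelial markers in 4T07 and on matrix genes in D2A1.

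Among 178 groups of 4 tumours or libraries, 13 held a value far from the other 3 by Dixon's criterion, and chance alone gives about 5%. The D2A1 p27K negative library of tumour 4 held 15641189 counts, far above its group. In 4T07, Rpl5 stood at a log2 difference of 0.92 in tumour 2, Cxcl16 at -2.39 in tumour 3 and the median of MHC class II genes at -1.59 in tumour 2. In D2A1, Cdkn1b stood at 0.64 in tumour 4, Neil3 at -4.70 in tumour 2, Tcof1 at -1.06 and Mmp3 at 2.37 in tumour 3. The medians of glycolysis enzymes (0.96) and of extracellular matrix genes (-0.28) also stood apart in D2A1 tumour 3. In EMT6 tumour 0, Abca1 (3.15), Kif11 (-5.28) and Aldoc (1.82) stood apart.

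The change between gates differed between lines for 3332 of 13578 genes, by a test of the difference in the joint fit, and for 75 of 110 named genes. Some named genes were chosen by this same test or as extremes of a single line, so their share does not describe genes at large. Each value is the largest difference of log2 change between a pair of lines. For genes of the cell cycle these were Espl1 (4.21), Ccdc18 (3.81), Cit (3.41), Bard1 (3.10), Pif1 (2.63), Ncapg (2.13), Pbk (1.89), Kif18b (1.88), Rrm2 (1.80), Pimreg (1.59), Kif11 (1.43), Nusap1 (1.38), Racgap1 (1.36), Mki67 (1.18), Clspn (1.16), Bub1b (1.11), Cenpe (1.06), Rrm1 (1.05), Mcm10 (1.04), Tpx2 (0.92), Ncapd2 (0.88), Cdca8 (0.80) and Kif23 (0.73). For other named genes they were Csf3r (6.42), Ptgs2 (4.84), Col5a2 (4.63), Ctgf (3.81), Tyrobp (3.75), Anpep (3.08), C1qb (2.47), Galnt15 (2.35), Aldoc (2.30), Saa3 (2.29), Lcn2 (2.25), Ogn (2.25), Dcn (2.07), Cxcl16 (2.02), Il13ra2 (1.91), Gstcd (1.81), Thbs2 (1.74), Vsir (1.69), Nos2 (1.64), Slc6a2 (1.60), Hsd11b1 (1.55), Tgfbr3 (1.497), H2-Aa (1.49), Mmp2 (1.28), Ctsa (1.25), Itgb8 (1.19), Cxcl10 (1.17), Car9 (1.11), Bnip3 (1.03), Abca1 (1.01), Dkc1 (1.00), Fdps (0.96), Tec (0.94), Slc2a1 (0.94), Ier3 (0.93), H2-Ab1 (0.91), Gas1 (0.86), Dnm1 (0.78), Ndrg1 (0.76), Psat1 (0.74), Eno2 (0.67), P4ha2 (0.64), Enpp2 (0.62), Sqstm1 (0.61), Gabarapl1 (0.61), Klf6 (0.58), Hk2 (0.56), Dusp6 (0.52), Dusp1 (0.52), Vegfa (0.48), Rpl5 (0.48) and Cdkn1b (0.40). Csf3r, Tyrobp, C1qb, H2-Aa and H2-Ab1 have few counts in at least 1 line, so their fitted values there carry little weight.

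Of 105 tests of a list between a pair of lines, 40 passed, over 22 lists, each given as the median over members of the difference in log2 change. For 4T07 minus D2A1 they were G1/S genes (-0.67), G2/M genes (-0.69), cholesterol synthesis (-0.60), MYC and ribosome biogenesis genes (0.43), cytosolic ribosomal proteins (0.19), unfolded protein and ATF4 response (0.19), extracellular matrix genes (0.24), epithelial genes (1.61), chemokines and cytokines (-0.63), interferon response (0.25), NF-kB targets (-0.47) and macrophage and monocyte markers (-2.20). For 4T07 minus EMT6 they were G1/S genes (-0.35), G2/M genes (-0.73), hypoxia targets (0.34), glycolysis enzymes (0.27), cholesterol synthesis (-0.46), MYC and ribosome biogenesis genes (0.32), unfolded protein and ATF4 response (0.16), checkpoint ligands and immunosuppressive factors (-0.18), chemokines and cytokines (-0.56), MHC class II antigen presentation (-0.82), macrophage and monocyte markers (-2.12) and endothelial markers (-1.05). For D2A1 minus EMT6 they were G1/S genes (0.21), G2/M genes (-0.12), CDK inhibitors and quiescence genes (0.24), hypoxia targets (0.29), glycolysis enzymes (0.37), oxidative phosphorylation (0.23), MYC and ribosome biogenesis genes (-0.14), cytosolic ribosomal proteins (-0.0598), p53 targets (0.23), autophagy and lysosome genes (0.16), extracellular matrix genes (-0.32), epithelial genes (-2.25), interferon response (-0.23), NF-kB targets (0.28), endothelial markers (-1.66) and pericyte and smooth muscle markers (-0.36). The joint tests held 26 epithelial and 13 endothelial members, of which 13 and 6 passed the filter on low counts in D2A1, where the epithelial median was -0.34 (0.61 with all libraries thinned), so these differences carry little weight. Endothelial markers had too few tested members in EMT6. The joint tests of chemokines and cytokines held 40 members, of which 24 passed that filter in D2A1 and 24 in EMT6, and among genes tested in all 3 lines their 4T07 median was -0.12, so the chemokine differences carry little weight too.

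Fewer genes were called in D2A1 (3794) than in EMT6 (6567). With EMT6 thinned to the totals of D2A1 libraries, 5277 genes were called, 1.39 times as many as in D2A1, within the bound set for depth beforehand. Lower depth may therefore account for part of the gap, but thinned EMT6 still called more. The biological coefficient of variation of D2A1 was 2.43 times that of thinned EMT6 (0.140 against 0.0578). It was estimated with the tumour as a block, so it covers variation of the gate difference and not differences in level between tumours. The coefficient was 0.0724 in EMT6 before thinning. In 4T07, which had deeper libraries and 5868 genes called, it was 0.146, so variation of this size was not particular to D2A1. A larger variation of the gate difference in D2A1 than in EMT6, biological or technical, is a second candidate explanation. Calls of at least 2-fold went the other way (1094 in D2A1, 867 in EMT6), so these counts do not point to a smaller response in D2A1, and other differences between the lines stay open, as untested.

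Macrophage transcripts were lower in p27K high cells of 4T07 (median -2.47), with Lyz2 at a mean of 194 CPM, Apoe at 125 and C1qa at 79.7 in the negative gate, all 3 chosen after their values were seen. Of 31 tested members of the other fixed immune lists 16 fell and 0 rose by edgeR (median -1.43), though camera called the neutrophil list and not the dendritic or T and NK lists, so host immune cells in the negative gate may explain the pattern. Whether that gate held more host cells of every type cannot be told apart from this: endothelial markers (median -0.89, 6 of 11 fell, 0 rose) go with it, fibroblast markers (median 0.45, 7 of 17 rose, 1 fell, with a median level of 8.79 CPM in the negative gate) go against it, and expression of the latter by tumour cells was not tested. The CD45 stain should have allowed such cells to be left out, but how it was gated is not stated. Ptprc, the CD45 gene, stood at 29.6 ± 8.07 CPM in the 4T07 negative gate and 7.80 ± 3.54 in the high gate (SD, n = 4). Its transcripts were thus counted in both gates, with more in the negative one, and it too was chosen after its values were seen. Expression of these genes by the tumour cells themselves was not tested.

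In D2A1, 15 matrix genes fell (median -1.94). At equal depth all 9 of the 15 that could still be tested fell (median -1.80). Medians of the 15 in the single tumours were -2.52, -1.44, -2.74 and -2.43. These genes were picked for falling in the same libraries, and thinning retested only those that still passed the filter on low counts. The retest therefore cannot decide whether shallow negative libraries contributed. Whether stromal fibroblasts in the negative gate may carry these transcripts cannot be told apart from a change in tumour cells. Fixed fibroblast markers outside the matrix list had a median of 0.48 over 13 tested, with 6 rises and 2 falls. The falls, Pdpn (-3.92) and Cd34 (-3.05), were named after their values were seen. Both were low even in the negative gate of D2A1 (7.68 ± 9.65 and 4.06 ± 1.44 CPM, SD, n = 4). Markers of that cell type thus went both ways, but the falls carry little weight. With all libraries thinned to the smallest, the whole fibroblast list was called up (median 0.69).

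Of 35 splits of the 8 libraries of each line, 3 could not be fitted and 1, the real split, gave as many genes (5868 in 4T07, 3794 in D2A1 and 6567 in EMT6), with 0 as the highest of the others. Most of these splits ignore the pairing by tumour. The 8 that part all 4 pairs, as the real one does, are too few for a share under 0.05, and the highest of the others was 0. For the average, where gates were swapped within tumours, 1 of 40 drawn splits, the real one, gave as many genes (7110, highest other 3143), and for the difference between lines 1 of 40 (3332, highest other 11). A share of 1 of 40 is under 0.05 and is the smallest that such a draw can give. Swapped gates keep part of the real contrast, so 3143 is not a count for unchanged data. Chance is argued against for both but not excluded. For the difference, line, sequencing run and the other form of the 4T07 count table cannot be told apart.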

How the results depend on the processing

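No list, and no gene that the naming rule took, reversed a called direction under the alternatives run for it. Single genes were not rerun under total count scaling, changed filters or voom, nor lists under the DESeq2 test, voom or no filter. Other genes were not checked for reversal. Under total count scaling 4939 of the 5868 calls of 4T07 kept their call and sign. All alternatives were planned before the data were examined except thinning, the restriction to genes tested in all 3 lines and total count scaling for lists, which were chosen after seeing the data. Where a value below is lower, fewer genes or stricter criteria produce it by construction or the cause was not tested. Requiring a log2 change of at least 1 left 1720 genes in 4T07, 1094 in D2A1, 867 in EMT6, 1210 in the average, 1228 for the difference between lines and 450 shared by all 3 lines (1727 without it). Lists called with an estimated correlation were 2, 0, 2 and 5 in 4T07, D2A1, EMT6 and the average, and fry called 27 in 4T07 and 25 in the average. The difference between lines gave 1607 genes without the replicate block and 6023 with voom. Without the block the genes called were 4407, 3563, 4471 and 6253, and 12, 13, 13 and 9 lists were called. That fit ended 10 list calls, moved only the difference between lines by over 1.5 times and changed no other count beyond that. Leaving out a tumour gave 3698 (without 1) to 7727 genes in 4T07, 2444 (without 1) to 5051 in D2A1, 5084 to 6984 in EMT6, 6502 to 7650 in the average and 2506 to 3733 for the difference. The lists called ranged from 13 to 15, 13 to 15, 16 to 18 and 11 to 12. DESeq2 gave 6169, 3460, 5409 and 7347 genes. D2A1 at equal depth gave 2796 genes, 2630 of them shared with the same sign, and 4T07 restricted to genes tested in all 3 lines gave 4954. Of values of genes that the naming rule took, 1308 kept direction and call and 1 lost its call, Cdkn1b in D2A1 without tumour 4. Of list tests 1524 kept direction and call, 53 of these with a median of the other sign, 70 lost a call, 48 of these under an estimated correlation, and 51 gained one, 34 of these under fry. Of the 3 lines, depth is lowest in D2A1, where 3 negative libraries hold 1335433 to 2110563 counts.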

Other observations

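Camera called none of the following lists in the lines named. In D2A1 the p53 targets had a median of 0.39, and 12 of 28 tested members rose, 2 fell and 14 did not pass the test (13 rose and 2 fell adjusted over the list alone). They had medians of 0.05 in 4T07 (-0.09 under scaling by total count) and -0.05 in EMT6. Stemness genes had medians of 0.17, 0.18 and 0.23 in 4T07, D2A1 and EMT6, also without a call. Epithelial genes were not called either (-0.19, -0.34 and 0.07). MHC class I genes, which present antigen to cytotoxic T cells, had medians of -0.15, -0.05 and -0.10, and interferon response genes 0.15, -0.17 and 0.11, with no call by camera in any line. Interferon response genes of EMT6 were called up without tumour 1 (median 0.17). Without tumour 4, the D2A1 medians of MHC class I and interferon response genes were 0.087 and 0.081. The D2A1 epithelial median was 0.61 with all libraries thinned to the smallest, a choice made after seeing the data.

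Markers of other cell types that were tested in 4T07 without a call were dendritic cell (-1.62), T and NK cell (-1.14), endothelial (-0.89), pericyte (-0.22, or 0.097 without tumour 1), adipocyte (0.09, or -0.043 under scaling by total count) and skeletal muscle markers (0.33, with a mean of -0.35). Fry, which does not compare a list with other genes, called the first 3 down (adjusted p = 0.00496, 0.00483 and 0.00753). In D2A1 macrophage markers had a median of -0.63 and in EMT6 -0.12, neither called, and both list tests pointed up. With a stricter filter on low counts these medians were 0.14 and 0.20. Of 9 tested MHC class II genes of EMT6 0 rose and 7 fell, with a median of -0.55 and no call. Mitochondrially encoded genes were measured in D2A1 (0.26) and EMT6 (0.14), and nuclear-retained RNAs in 4T07 (0.66) and D2A1 (0.19), with no call. The means of nuclear-retained RNAs were -0.00138 and -0.48, and that of p53 targets in 4T07 was -0.05. The D2A1 tests of epithelial and MHC class I genes pointed up, against their medians.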
